A study of Arabidopsis thaliana with 6 samples.

How the data were processed

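The series mapped FLAG-tagged EBS by ChIP-seq in Arabidopsis seedlings, with 3 ChIP and 3 input DNA samples. The grouping and the replicate numbers came from the labels. Per the submitters' processing notes, Bowtie2 2.2.8, SAMtools 1.3 and MACS 1.4 were used with genome build TAIR10. How the input entered peak calling and which threshold was set are not given in the sources used here. The authors deposited 1 peak list per ChIP sample, so peaks were called per sample and not on pooled reads. Each deposited list gives, for every peak, its start and end and a score, which in output of this caller is 10 times the negative log10 of the peak's p-value. The lowest score in the lists was 20.0, which would correspond to a p of 0.01. Ties at 3100, with a few values above it, mark the upper end of the scale, and scores were capped at 3100 for percentiles. Scores move with depth and with the control, so they were used only to describe, rank or filter peaks within a list.

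Depth could not be read from the lists, and the numbers of peaks say nothing certain about it. A loose threshold lets in weak peaks: 27.5%, 32.0% and 50.4% of nuclear peaks had a score of at least 100 in replicates 1, 2 and 3. No pair of lists was a copy of another, since at most 1 peak of any pair had the same start and end. Chloroplast and mitochondrial peaks were left out of all comparisons. Coordinates in the text are those of the lists on TAIR10, counted from 1.

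Gene positions came from a RefSeq gene table of assembly TAIR10.1, whose nuclear coordinates were taken to be those of TAIR10. This was checked by shifting the reproducible regions: 73.9% of midpoints lay in a gene without a shift, against 57.4% to 62.2% with shifts of 1000 to 50000 bp. None of the table's coordinates is printed, and distances to genes rest on that shared frame. The table held 27444 protein-coding genes, 4843 pseudogenes and 5612 non-coding RNA genes on the nuclear chromosomes, with no strand and no exons. All 177 genes of the fixed lists were matched by locus tag.

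Peaks of the 3 lists were merged where they shared at least 1 bp, and a merged region with a peak of all 3 lists was called reproducible. Overlap and location were tested against 1000 random placements on the same chromosome with lengths kept. Location classes were given in the order flank (1000 bp on either side of a protein-coding gene), gene body, non-coding RNA gene, pseudogene and intergenic. Gene-poor bins were the 119 of 1193 bins of 100 kb with the least protein-coding cover. A gene counted as holding a region when the region overlapped the gene or 1000 bp on either side. Each of 12 gene lists and 17 symbol families was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 29 together. That test treats genes as independent, although neighbours can share a region. Exact Clopper-Pearson intervals (95%) describe the number of genes in a list and no other error. Scores in and outside reproducible regions were compared by a permutation test of medians with 100000 resamples.

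The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named EBS, SHL, FT, SOC1 and FLC, every floral activator or repressor with a reproducible region, the 10 genes with the highest mean score percentile, and up to 4 genes with and 2 without a region from each other list. Because 29 genes tied for the 10 places, ties were ordered by the bases covered by the list with the least cover there, a choice made after the data were seen. A region was given to the gene with the most overlap. CRU2, LHCA2, LHCA4, PSAD1, RBCS2B, SWN, RGA, GRP2, the members of symbol families and prefixes and the genes with peaks in replicate 1 alone were named after their values were seen.

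Several steps departed from the fixed design because the table has no strand or exons and no genome sequence was used here. A flank on both sides replaced the upstream promoter, either gene end replaced the transcription start, and UTR, exon and intron classes were not analysed here. A region on a neighbouring gene can therefore count for a gene whose promoter it does not touch. Sequence motifs and the assignment by distance to the transcription start were not run. Alternatives were a score of at least 100, an overlap of at least 50% of the shorter peak, presence in at least 2 lists, leaving out each replicate, lists of equal length (3661 peaks), a 500 bp flank, gene body before flank, covered bases, gene body only, random placement outside gene-poor bins, and 10000 random gene lists matched on gene length in 20 bins. The comparison by score class, the use of single lists, the symbol prefixes, an exact length-matched calculation and the location classes outside and inside gene-poor bins apart were added after the data were seen.

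The code was tested on simulated lists of the real lengths: all 1500 shared regions placed were recovered (100%), and unrelated lists gave 18 reproducible regions. The shared regions were put in every list with shifts smaller than their widths, so their recovery was assured. It checks the code and says nothing about missed or weaker peaks. Of 40 simulated lists of 21 genes drawn from 27444, 10 had binding raised to 35%, of which 9 were called, and 0 of the others were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.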

Results

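EBS (EARLY BOLTING IN SHORT DAYS) is an Arabidopsis chromatin protein that delays flowering and binds methylated histone H3 tails. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Col-0 seedlings about 10 days old, grown in 16 h light and 8 h dark. The plants lacked EBS and its close relative SHL and carried FLAG-tagged EBS driven by its own promoter, and chromatin was collected with an anti-FLAG antibody. The series held 6 samples: 3 ChIP replicates, each with its own peak list, and 3 input DNA samples, for which no separate values were used here. The lists held 5240, 4219 and 3667 peaks in replicates 1, 2 and 3, of which 5237, 4216 and 3661 lay on the 5 nuclear chromosomes. Peaks covered 4.39, 4.47 and 2.71 Mb, with median widths of 699, 880 and 652 bp. A peak list holds no read counts, so the sequencing depth behind each list is unknown. Nothing in the labels says that the replicates came from separate plantings, so the spread between them may be technical.

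Which sites held a peak in every replicate was the question behind the comparison of the lists. No ChIP from plants without the tag was among the samples. A peak in every list can therefore be EBS or background that recurs in the procedure. Merging all peaks gave 7956 nuclear regions, and 1780 of them (22.4%) held a peak of all 3 lists. These reproducible regions covered 2.81 Mb and had a median length of 1336 bp, against 646 bp for the other regions. A further 579 regions were shared by replicates 1 and 2 alone, 256 by replicates 1 and 3, and 197 by replicates 2 and 3. Regions of a single list numbered 2375, 1541 and 1228 in replicates 1, 2 and 3. Over the 6 ordered pairs of lists, 52.8% ± 7.5 (SD, range 41.5% to 60.3%) of the peaks of a list overlapped a peak of another. Random placement on the same chromosomes gave 6.25%, an 8.44-fold difference, with a one-sided permutation p of 0.001 in every pair, the smallest that 1000 placements can give. The number of reproducible regions depended on the rule: 1086 were found when only peaks with a score of at least 100 were used, and 2812 regions were in at least 2 lists.

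**Figure D1:**
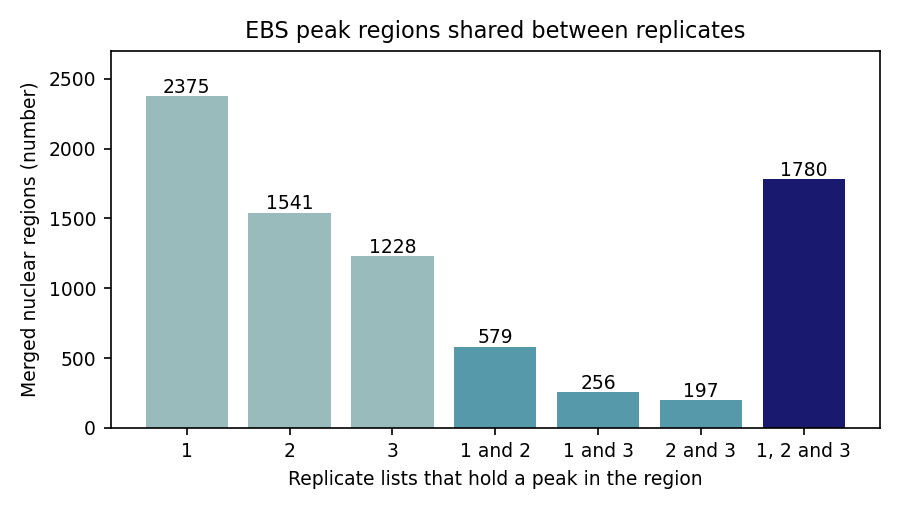
Number of merged nuclear regions (vertical axis) found in each combination of the 3 EBS:FLAG peak lists (horizontal axis). The 1780 regions of all 3 lists are outnumbered by the 2375 found in replicate 1 alone.

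Peaks in reproducible regions had higher scores than the other peaks of their own list. The median score was 219 in reproducible regions against 26.2 elsewhere in replicate 1, 226 against 27.1 in replicate 2, and 334 against 35.1 in replicate 3. The two-sided permutation p was 1e-05 in each list, the smallest that 100000 resamples can give. Of the peaks with a score of at least 100, 94.9%, 94.8% and 82.7% lay in reproducible regions in replicates 1, 2 and 3. Regions of replicate 3 alone included 141 with such a score, against 11 for replicate 1 and 6 for replicate 2. A fixed score does not cut the lists alike, since 27.5%, 32.0% and 50.4% of the nuclear peaks of replicates 1, 2 and 3 passed it, so these 3 counts do not compare the replicates. Scores are the authors'.

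The strongest reproducible regions, with a score of 3100 in all 3 lists, numbered 32, and 29 genes were tied at the highest rank. The 10 genes chosen among them by the bases covered were AT1G20400, AT3G22125, AT5G39770, AT2G47440, AT4G38670, LRX3 (AT4G13340), STN1 (AT1G07130), AT3G17060, AT3G28780 and AT5G11550. LRX3 encodes a leucine-rich repeat extensin of the cell wall, and its region spanned chromosome 4 from 7758160 to 7761742 (TAIR10). STN1 encodes a telomere-capping protein, with a region on chromosome 1 from 2186778 to 2190917. The longest of the 10 regions lay on AT1G20400, on chromosome 1 from 7065509 to 7076547. The region on AT4G38670, on chromosome 4 from 18069414 to 18074134, also covered GRP2, which encodes a glycine-rich protein. The best-scoring peaks counted for AT2G47440 lay off its body in all 3 lists, as did the replicate 3 peak counted for AT4G38670. Exon, intron and UTR positions were not analysed here.

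Where the regions sat relative to genes was compared with random placement. Pseudogenes, a class that here includes transposon-like loci, held 25.1% of the 1780 region midpoints against 8.2% ± 0.67 (SD over placements) at random, 3.05-fold more. The tenth of 100 kb bins with the least protein-coding sequence held 26.1% of the regions against 10.2% ± 0.72 at random (2.56-fold, permutation p = 0.002). Flanks of protein-coding genes, within 1000 bp on either side, held 26.3% against 37.9% ± 1.17, and gene bodies outside those flanks held 30.8% against 36.4% ± 1.14. The Benjamini-Hochberg adjusted two-sided permutation p was 0.0033 for pseudogenes, flanks and bodies, which rests on the smallest p that 1000 placements can give. Non-coding RNA genes held 0.8% against 0.6% (adjusted permutation p = 0.37) and intergenic sequence 17.0% against 16.9% (adjusted p = 0.98). Midpoints within 1000 bp of an end of a protein-coding gene made up 50.8% against 57.8% ± 1.2 at random (permutation p = 0.002).

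Counted by locus, reproducible regions overlapped 564 of 4843 pseudogenes (11.6%), 2.11-fold more than random placement gave, and 1290 of 27444 protein-coding genes (4.7%), 0.82-fold the random number (permutation p = 0.002 for each). The number of non-coding RNA genes overlapped, 160 of 5612, was 0.95-fold the random number (permutation p = 0.6). Without replicate 3, 37.1% of midpoints lay in gene bodies against 36.4% at random (adjusted p = 0.52), 57.8% lay near gene ends against 57.9% (permutation p = 0.87) and 13.6% were intergenic against 16.9% (adjusted p = 0.0033), whereas the pseudogene share was 20.9% against 8.2%. Placed at random only in bins of their own kind, a split chosen after the data were seen, the 1315 regions outside gene-poor bins had 39.8% in bodies (adjusted permutation p = 0.92; 59.4% against 59.5% with bodies counted before flanks), 65.9% near gene ends against 63.4% (p = 0.082) and 34.3% in flanks against 41.6% (adjusted p = 0.005), and the 465 inside had 5.2% in bodies against 4.0% (adjusted p = 0.3).

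**Figure D2:**
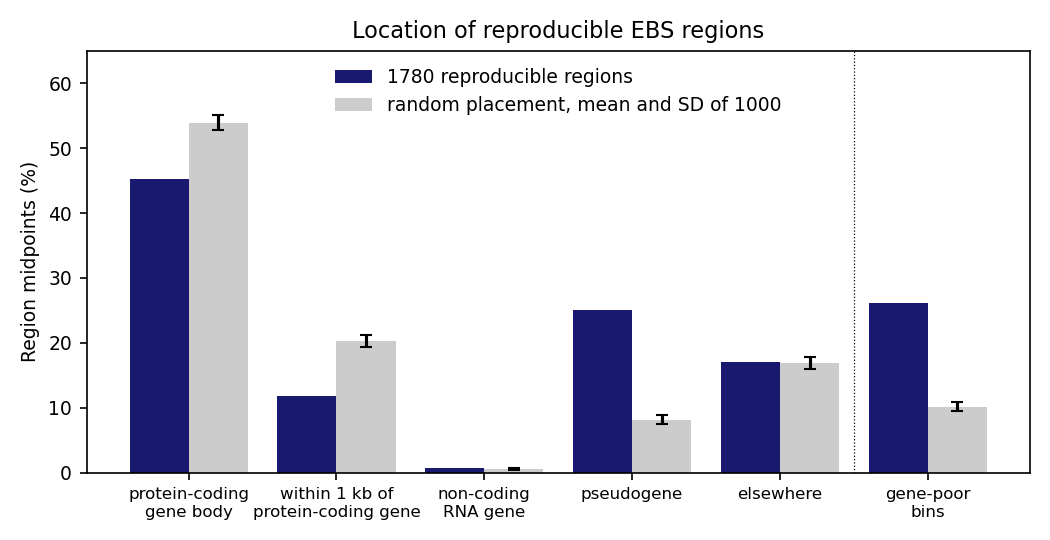
Share of reproducible region midpoints (vertical axis, percent) by location, with the gene body counted before its flank, beside the mean of 1000 random placements; error bars show the SD over placements. Pseudogenes hold 25.1% against 8.2% at random, and gene bodies hold 45.3% against 53.9%.

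The weak and the strong peaks of a list lay in different places. With gene bodies counted before flanks, bodies held 73.0% of the replicate 1 peaks with a score below 100 and 42.4% of those with a higher score, and in replicate 2 the shares were 73.2% and 44.2%. In replicate 3 they were 49.3% and 46.7%, which Fisher's exact test did not separate (adjusted p = 0.12). Pseudogenes showed the opposite order in all 3 lists: 28.4% of the strong against 6.7% of the weak peaks in replicate 1, 25.5% against 8.7% in replicate 2 and 26.4% against 15.3% in replicate 3 (adjusted p of 1.8e-86, 2.5e-45 and 6.6e-17). Over all peaks of a list, gene bodies held 58.8% ± 9.4 and pseudogenes 15.9% ± 4.4 (SD, n = 3). By replicate, bodies held 64.6%, 63.9% and 48.0%, and 67.5%, 67.1% and 56.4% lay near gene ends. Random placement of the reproducible regions gave 53.9% and 57.8% in the same class order. The whole lists of replicates 1 and 2 thus showed neither deficit, although single lists were not placed at random. This split by score was chosen after the data were seen.

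Flowering genes were the lists implied by the protein studied. Among 21 floral activators none held a reproducible region on the gene or within 1000 bp (exact 95% interval 0% to 16.1%), against 1832 of all 27444 protein-coding genes (6.68%). FT (AT1G65480), which encodes the mobile flowering signal, had no peak in any list. SOC1 (AT2G45660), a MADS-box activator of flowering, had peaks on its body in replicates 1 and 2 (chromosome 2, 18809917 to 18811070 with a score of 56.3, and 18809177 to 18811016 with 70.6). The replicate 3 peak near SOC1, at 18805847 to 18806651 with a score of 22.2, lay off its body and did not overlap the others, so SOC1 held no reproducible region. Fisher's exact test gave an adjusted p of 0.72 for the activators.

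Of 22 floral repressors, 4 were near a reproducible region: FLC, ATC, TEM1 and TEM2 (18.2%, exact 95% interval 5.2% to 40.3%). The odds ratio of 3.11 had an adjusted Fisher's exact p of 0.27 (unadjusted 0.055). TEM1 and TEM2, repressors of FT and of gibberellin synthesis, carried the region on the gene body. The TEM2 region (AT1G68840, chromosome 1, 25879832 to 25882366) had scores of 338, 563 and 2268 in replicates 1, 2 and 3, and the TEM1 region (AT1G25560, chromosome 1, 8981887 to 8983377) had 67.8, 111 and 23.3. The region counted for FLC (AT5G10140), a repressor of FT and SOC1, lay on chromosome 5 from 3170434 to 3172951 with scores of 1403, 1423 and 1168. It lay 430 bp outside FLC and mainly on the neighbouring gene AT5G10130, and its replicate 3 peak was more than 1000 bp from FLC. The region counted for ATC lay 568 bp outside that gene, on AT2G27580, likewise with no replicate 3 peak within 1000 bp of ATC. With gene bodies alone, neither FLC nor ATC held a region.

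Chromatin regulators, a list that includes EBS and SHL, held reproducible regions in 3 of 21 cases (14.3%, exact 95% interval 3.0% to 36.3%, adjusted Fisher's exact p = 0.37). REF6 (AT3G48430), a histone demethylase, carried scores of 1169.8, 1297 and 1036 over chromosome 3 from 17934787 to 17936806. SHL (AT4G39100) carried scores of 85.8, 780.2 and 34.5 over chromosome 4 from 18214902 to 18220212. This region was lost with a score of at least 100 and with an overlap of 50% of the shorter peak. The plants lacked SHL, and how that locus was altered was not analysed here. The region counted for VIN3, which acts in the response to winter cold, lay 431 bp outside it, on AT5G57370, and replicate 3 had no peak within 1000 bp of VIN3. EBS itself (AT4G22140) had peaks with scores of 236 and 117 in replicates 1 and 2 and none in replicate 3; the locus and the tagged transgene share sequence, and a peak list does not separate them. In single lists, 12, 6 and 2 of the 21 genes had a peak on the gene or within 1000 bp in replicates 1, 2 and 3, where 20.8%, 17.1% and 11.7% of all genes did. Fisher's exact test against other genes gave an adjusted p of 0.0028, 0.48 and 1, and the difference between replicates was not tested. CLF and SWN, catalytic subunits of Polycomb repressive complexes, had peaks in replicate 1 alone, with scores of 297 and 618.

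Photosynthesis genes held reproducible regions more often than other genes: 7 of 21 (33.3%, exact 95% interval 14.6% to 57.0%) against 6.7%. The odds ratio was 7.01, with an adjusted Fisher's exact p of 0.0086 over all 29 lists and families, or 0.0035 adjusted over the 12 lists alone. The 7 genes were LHCB1.3, LHCB2.1, LHCB4.1, LHCB6, LHCA2 and LHCA4, which encode light-harvesting proteins, and PSAD1, which encodes a subunit of photosystem I. LHCB6 had scores of 2232, 2842 and 2417 in a region on chromosome 1 from 5445372 to 5450997 that lay mainly on AT1G15830. The region counted for LHCB1.3, with scores of 51.9, 139 and 21.3, lay mainly on the neighbouring gene NRPA2. PSAD1 (chromosome 4, 1228297 to 1230296) had 1107, 665 and 3100, whereas LHCB2.1 had 97.2, 81.7 and 31.7. Single lists had peaks at 20, 18 and 8 of the 21 genes in replicates 1, 2 and 3 (73.0% ± 30.6, SD, n = 3), against 16.6% ± 4.6 of all genes (adjusted Fisher's exact p of 1.1e-11, 3.6e-10 and 0.026). LHCB1.1 and LHCB1.2, neighbours without a reproducible region, had scores of 36.2 and 266 from shared peaks in replicates 1 and 2, and LHCB1.2 alone had 146 in replicate 3. RBCS2B, which encodes a small subunit of Rubisco, had no peak in any list. Without replicates 1, 2 and 3, 7, 7 and 18 of the 21 genes held a region (adjusted Fisher's exact p of 0.013, 0.013 and 1.2e-14). The result rested on weaker peaks, since 2 of 21 genes held a region when every peak needed a score of at least 100 (adjusted Fisher's exact p = 0.71).

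**Figure D3:**
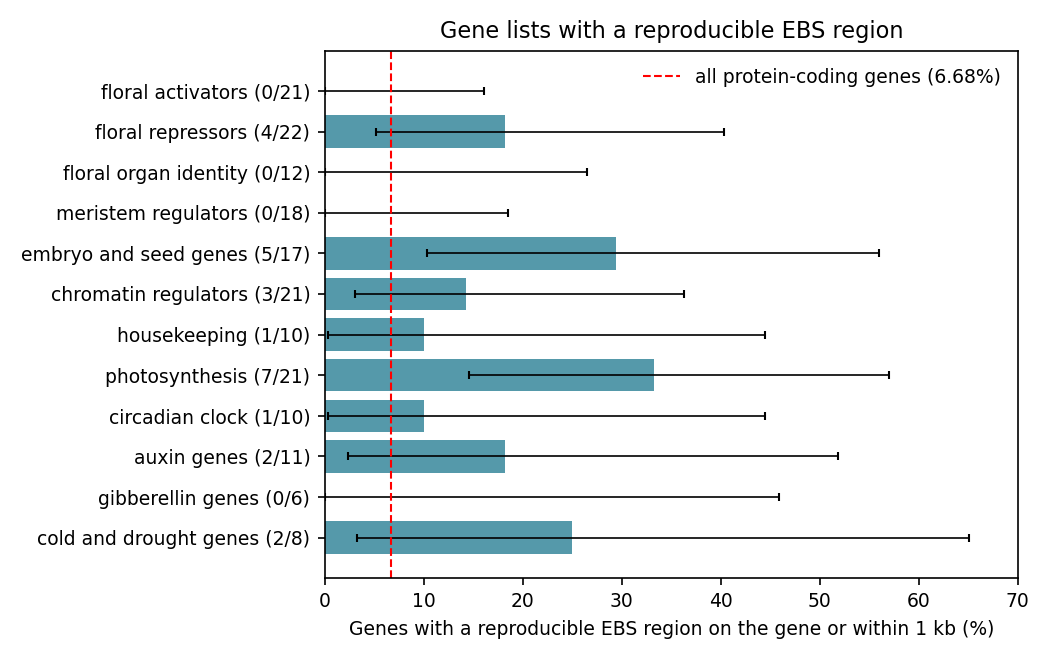
Share of each list's genes with a reproducible region on the gene or within 1 kb (horizontal axis, percent; bars), with exact 95% binomial intervals over the genes as error bars and the share of all protein-coding genes, 6.68%, as a dashed line. Photosynthesis genes, at 33.3%, have an interval that starts at 14.6%.

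Embryo and seed genes held regions in 5 of 17 cases (29.4%, exact 95% interval 10.3% to 56.0%). The odds ratio was 5.84, with a Fisher's exact p of 0.06 adjusted over all lists and families and 0.025 adjusted over the lists alone. The seed storage genes CRA1 (AT5G44120) and CRU2 (AT1G03880) had scores of 504, 792 and 784, and of 831, 1151 and 1110.0. The best-scoring CRU2 peaks lay off its body in all 3 lists, in a region mainly on AT1G03890. ABI4, a regulator of abscisic acid responses, had 573, 650.4 and 812 on chromosome 2 from 16795111 to 16798844. LEC1, a regulator of embryo development, had 149, 38.2 and 40.5, and the region counted for DOG1, a seed dormancy gene, lay 796 bp outside it, on CIPK20, with no replicate 3 peak within 1000 bp of DOG1. LEC2 had no peak, and FUS3 had peaks within 1000 bp in replicates 2 and 3 alone. Peaks were found at 6, 7 and 8 of the 17 genes in replicates 1, 2 and 3 (41.2% ± 5.9, SD, n = 3; adjusted Fisher's exact p of 0.34, 0.12 and 0.0094). The adjusted Fisher's exact p over all lists was 0.013, 0.013 and 0.077 without replicates 1, 2 and 3 and 0.25 at a score of at least 100 (3 of 17), and the adjusted permutation p against length-matched random lists was 0.13.

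**Figure D4:**
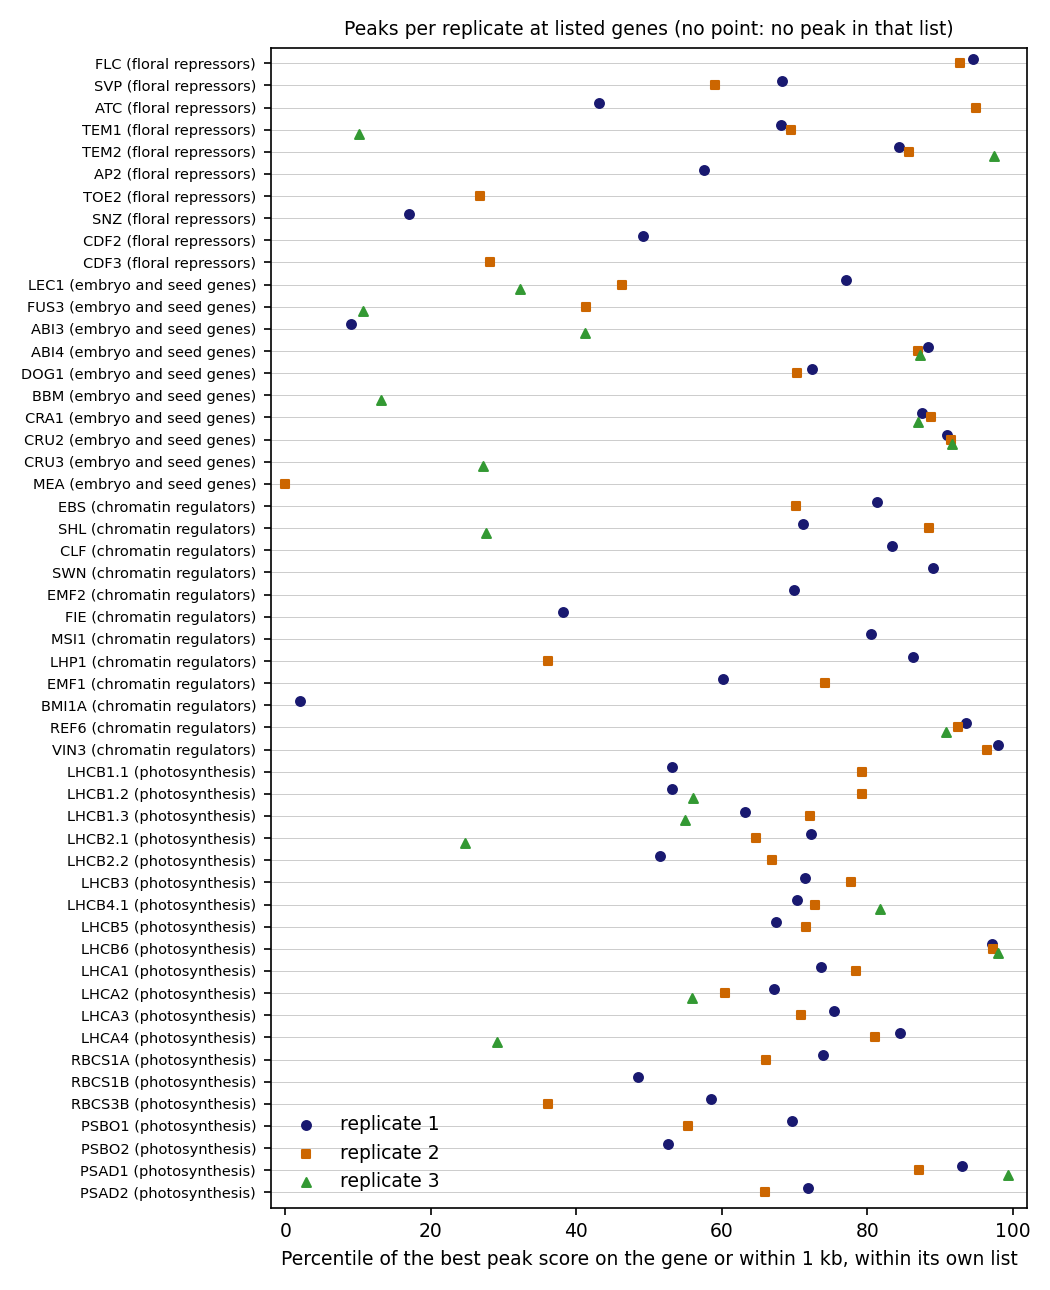
Percentile of the best peak score within its own list (horizontal axis) for genes of 4 lists, 1 point per replicate and no point where that list had no peak on the gene or within 1 kb. Replicate 3 points are absent at most photosynthesis genes, and CLF and SWN have replicate 1 points alone.

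Floral organ identity genes (0 of 12, among them AG and AP3) and meristem regulators (0 of 18, among them STM and KNAT1) held no reproducible region. Neither did the gibberellin genes (0 of 6), of which GA3OX1 and GA20OX1 had no peak, while the growth repressor gene RGA had scores of 269 and 76.5 in replicates 1 and 2. Auxin genes held 2 of 11, the biosynthesis gene YUC6 with scores of 276, 229 and 877 and the transporter gene PIN4 with 87.9, 29.6 and 47.2 (the replicate 3 peak off its body), while YUC1 and YUC2 had no peak. Clock genes held 1 of 10, ZTL, a blue light receptor gene, in the region also counted for VIN3, with scores of 2680.0, 2466 and 1847, while CCA1 and LHY had no peak. Housekeeping genes held 1 of 10, UBQ10, with no peak at the actin genes ACT2 and ACT7, and cold and drought genes 2 of 8, COR47 and COR15A, of which the region counted for COR15A lay 770 bp outside it on COR15B, and COR15A had a peak within 1000 bp in replicate 1 alone. CBF1 and CBF2, regulators of cold responses, had peaks in replicates 2 and 3 alone, with scores of 21.6 and 123 and of 34.3 and 76.6. The adjusted Fisher's exact p of these 7 lists lay between 0.35 and 1.

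Symbol families held only genes whose symbol or a synonym matched a set pattern, so they can leave members out. Of the 17 symbol families, none differed from other genes in reproducible regions past the adjusted threshold of 0.05. An unadjusted Fisher's exact p under 0.05 was found for 3. ERF genes, which encode ethylene response factors, held 6 of 27 (22.2%, adjusted Fisher's exact p = 0.074) and TCP genes, which encode growth-related transcription factors, 5 of 22 (22.7%, adjusted p = 0.097). ERF4 reached a score of 3100 in all 3 lists, and TCP10 had 2381, 3197 and 1614, of which the replicate 2 peak alone reached its body. Cytochrome P450 genes held 7 of 234 (3.0%, adjusted Fisher's exact p = 0.1), NAC genes 2 of 100 (adjusted p = 0.28) and MYB genes 4 of 125 (adjusted p = 0.37). The remaining families were MADS-box (7 of 98), WRKY (6 of 72), homeobox (6 of 47), F-box (4 of 31), ribosomal protein (4 of 67), SAUR (3 of 80), heat shock protein (2 of 31), IAA (2 of 32), SPL (1 of 18), bHLH (0 of 22), histone (0 of 20) and pentatricopeptide repeat (0 of 12). In single lists, a use chosen after the data were seen, 4 families passed the threshold in 1 replicate each. Homeobox genes had peaks at 21 of 47 in replicate 1 (adjusted Fisher's exact p = 0.0028) and MYB genes at 13 of 125, fewer than other genes (adjusted p = 0.02), while in replicate 2 TCP genes had peaks at 14 of 22 (adjusted p = 2.2e-05) and ERF genes at 14 of 27 (adjusted p = 0.00038).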

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

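Peaks on the organelle genomes, which no comparison above used, reached high scores, and no test was run on them. The highest chloroplast score was 67.1 in replicate 1, 3228 in replicate 2 and 3100 in replicate 3. In replicates 1 and 2 the chloroplast held a single peak, from 1 to 84366 and from 1 to 84365, and in replicate 3 it held 2 peaks, from 1 to 30339 and from 30570 to 84398. The highest mitochondrial score was 516 in replicate 1, 701 in replicate 2 and 1162 in replicate 3. That mitochondrial peak lay at about the same place in each list, from 232916 to 233342, from 233015 to 233336 and from 232953 to 233336. Scores were not compared between lists, and no explanation for the organelle peaks was tested.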

How the results depend on the processing

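No paired analysis was possible because the input samples that share the replicate numbers had no values used here. Overlap between replicates, the surplus in pseudogenes and gene-poor bins and the higher scores of reproducible regions kept their direction and their side of the threshold under every alternative run for them, and the deficit in flanks did so except inside gene-poor bins (3.7%, random 5.7%, adjusted permutation p = 0.09), but by covered bases it was small (35.5% against 37.9%). With a score of at least 100, there were 1086 reproducible regions, 1071 genes with a region and 0 lists or families above other genes, so the photosynthesis call was lost (2 of 21, adjusted Fisher's exact p = 0.71, against 1.2e-14 to 0.046 under the other alternatives). The stricter score leaves fewer peaks by construction. With regions in at least 2 lists there were 2812 regions, 3109 genes and 5 lists or families above other genes; the deficits in gene bodies (37.4%, random 36.4%, adjusted permutation p = 0.26) and near gene ends (58.5%, random 57.9%, permutation p = 0.56) ended, intergenic sequence fell below random placement (13.4%, random 16.9%, adjusted permutation p = 0.0033), and the cause was not tested. Leaving out 1 replicate gave 1990 to 2372 regions, 32.0% to 37.1% in gene bodies, 13.6% to 16.6% intergenic, 52.1% to 57.8% near gene ends, 1982 to 2626 genes and 2 to 4 lists or families above other genes. The body share of 37.1%, the intergenic share of 13.6% and the gene-end share of 57.8% were those without replicate 3, which ended the deficits in bodies and near gene ends; the cause was not tested. Intergenic sequence, at the random level in the main result, was below it with a 500 bp flank (20.4% against 23.3%) and by covered bases (12.9% against 16.9%), and the cause was not tested. With placement only in bins of the same kind, chosen after the data were seen, the deficits in bodies and near gene ends were past the threshold neither outside gene-poor bins (39.8%, adjusted permutation p = 0.92, and 65.9% against 63.4%) nor inside them (5.2% against 4.0% and 8.4% against 8.9%), and intergenic sequence was below random inside them (32.9% against 48.4%, adjusted permutation p = 0.005). The number of lists or families above other genes was 2 with an overlap of 50% of the shorter peak, 2 with lists of equal length and 3 with gene bodies alone, against 1 in the main result. Embryo and seed genes passed the threshold under 5 alternatives (adjusted p from 0.012 to 0.049) and not under the other 4 (0.051 to 0.25), and ERF and TCP genes under 4 each (0.0045 to 0.025 and 0.0045 to 0.03). Homeobox genes passed without replicate 3 (0.03) and cold and drought genes with regions in at least 2 lists (0.046). Of 35 named genes with a region, 19 kept it under all 8 settings, 13 lost it with a score of at least 100 and 5 with gene bodies alone. Motifs and distances to the transcription start were not run, and unknown depth limits every comparison between lists.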

Other observations

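The tests of symbol prefixes, of ribosomal protein genes, of gene ends of replicate 1 regions, of chance misses and of lists on single-replicate regions were chosen after the result was seen. The cluster test of photosynthesis genes and the test of the pseudogene share outside gene-poor bins were set down before their own results were seen. Neither of them is among the alternatives listed above as fixed before the data were examined. Length-matched lists and the score of at least 100 were alternatives fixed before the data were examined, but were taken up against these explanations after their values were seen. Genes for glycine-rich proteins stood out among 174 symbol prefixes shared by at least 10 genes. Of 16 GRP genes, 13 held a reproducible region (81.2% against 6.6% of other genes, adjusted Fisher's exact p = 4e-11). Among all 16, 13, 13 and 12 had a peak in replicates 1, 2 and 3. The region counted for GRP4 lay 887 bp outside it, mainly on GAE6, and GRP4 had a peak within 1000 bp in replicate 1 alone. GRP17 had a peak in replicate 2 alone, which it shared with GRP14 and GRP18. GRP7, which encodes an RNA-binding protein under clock control, had a score of 3100 in all 3 lists (chromosome 2, 9264205 to 9266762). A cluster on chromosome 5 held 6 of the 13; counting the leading gene of each cluster alone, 8 of 11 held a region (unadjusted Fisher's exact p = 5.3e-08). AGP genes, for arabinogalactan proteins of the cell surface, held 9 of 30 (adjusted Fisher's exact p = 0.0089), with AGP4 and AGP11 at 3100 in all lists. The prefix ERF held 7 of 25 (adjusted Fisher's exact p = 0.042), and CAT, which mixes catalases with amino acid transporters, 5 of 11 (adjusted p = 0.025), of which CAT1 and CAT3 share a region. With the leading gene of each cluster alone, CAT held 4 of 10 and ERF 6 of 22 (unadjusted Fisher's exact p of 0.003 and 0.0026). With a score of at least 100, 3.9% of all genes held a region, and GRP stayed past the threshold (11 of 16, adjusted Fisher's exact p = 1.9e-10). AGP (6 of 30, adjusted Fisher's exact p = 0.08), CAT (3 of 11, 0.3) and ERF (5 of 25, 0.14) did not.

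Photosynthesis genes held regions more often than other genes, and technical explanations were set against that pattern. Gene length alone is argued against by a small margin: the adjusted permutation p was 0.046 against random lists of matched length and 0.025 when computed exactly, a calculation added after the former was seen. A signal common to all strongly transcribed genes was set against ribosomal protein genes, a family picked by symbol. Of these, 4 of 67 held a region, fewer than photosynthesis genes (Fisher's exact p = 0.0031). RPL12-B and RPL12-C were counted through the same region. Transcript levels were not analysed here, so the families are not matched in transcription and the comparison cannot decide. A signal at all or only some strongly transcribed genes stays open. Housekeeping genes held 1 of 10, histone genes 0 of 20 and GRP genes 13 of 16, but their transcription in these seedlings is unknown here. Neighbours sharing a region do not account for the photosynthesis pattern: with 1 gene kept per cluster, 6 of 17 held a region (Fisher's exact p = 0.00057). The loss of the call at a score of at least 100 (2 of 21 genes, adjusted Fisher's exact p = 0.71) leaves a background signal at these genes open, and no biological explanation was tested.

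The 8 regions of replicate 1 alone with a score of at least 150 lay on HSL1 (664), SWN (618 and 159.6), CLF (297), HSI2 (229 and 211), MSI1 (212) and PG2 (155), of which SWN, CLF and MSI1 are in the list. Over all regions of replicate 1 alone, whatever their score, 7 of the 21 chromatin regulators held one on the gene body. That did not pass the threshold (Fisher's exact p = 0.067, adjusted over 261 tests). Among regions with a score of at least 50 and 100, 4 and 3 of the 21 held one (adjusted Fisher's exact p of 1.4e-05 and 5.6e-06). These were the only 2 of the 261 tests above other genes. Their score cutoffs were chosen after the data were seen. They include the strong regions named first, so they only describe that pattern. Chance misses in the other lists stay open. Of replicate 1 peaks with a score of at least 150, 99.3% (1190 of 1198) overlapped a peak of another list. The remaining 8 are the very regions named first, so the share excludes nothing. Cloned copies of these genes among the sequenced DNA may be a source, and 7 of 7 replicate 1 regions on these regulators with a score of at least 50 ended inside the gene, but so did 34 of 47 others (72.3%, one-sided Fisher's exact p = 0.13). With 7 of 7 this test was already at its maximum and could not have passed, so it decides nothing, and no biological explanation was tested.

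Reproducible regions lay on pseudogenes more often than random placement gave. Location in the gene-poor bins alone is argued against. Outside them the pseudogene share was 13.7% against 4.5% at random (permutation p = 0.002), and inside them 57.4% against 41.3%. Placement within either kind of bin was not matched on gene cover. A lean toward the poorer of the remaining bins therefore stays open. Weak peaks let in by a loose threshold are argued against as well, since regions built from peaks with a score of at least 100 had a share of 26.9%. Reads that match several repeats stay open, since read alignments were not analysed here. No biological explanation was tested.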
